A study of Mus musculus with 12 samples.

How the data were processed

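RNA was extracted from dorsal hippocampus with Trizol and a column cleanup, and libraries were made from 250 ng of total RNA with the TruSeq RNA v2 kit, which does not mark strand. The deposited table holds raw counts of reads per Ensembl gene, and the genome build is mm10, per the labels. The aligner, the counting software's version and settings, the gene annotation and the read length are not given in the sources used here. Counting of a read that fits several genes is not given either, so genes with near-identical copies are uncertain.

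The table has 52634 genes and 0 entries that name no gene, and 0 columns were left unmapped to a sample. Symbols were found for 52401 gene identifiers, 233 had none, and 52487 identifiers matched the GENCODE M21 annotation of GRCm38, from which coordinates, exon lengths and GC content were taken. Library totals were 18747249 to 25522347 counts, so that 3 counts, taken as the upper limit allowed by a count of 0, equal 0.118 to 0.160 CPM. Such limits cover counting error only.

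Groups came from the labels: genotype and sex, with 3 libraries each. Genes were kept by edgeR's filterByExpr, which left 17631, scaled by TMM and tested by the quasi-likelihood F test with robust dispersion in edgeR 4.0.16 under R 4.3.3, with all 12 libraries in 4 groups. The contrasts were genotype within each labelled sex, their difference and mean, and labelled sex within each genotype. Adjusted p is by the Benjamini-Hochberg method with a threshold of 0.05. SE is the absolute log2 fold change over the square root of F. Group means in CPM are scaled by TMM, except those of Slc6a4, which like all CPM values of single libraries use library totals. A total of 39 gene lists, 20 of cell types and 19 of functions, was fixed before the data were examined. Lists with at least 5 measured genes, 38 of them, were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and an inter-gene correlation preset at 0.01. Estimated correlations and fry served as alternatives. Where fewer than 5 genes passed, the 10 with the smallest p were named. The fit of the labelled-female libraries alone was an alternative fixed beforehand. Its named genes are the 10 largest increases and 10 largest decreases among genes past the threshold, with mean log2 CPM of at least 1 and groups that did not overlap. Up to 4 members with the smallest p were named for a list. Predicted gene models were passed over. Some genes that the rule takes are not reported here. List members named from the labelled-female fit, and Leng8 and Mbd6 shown with full values, were chosen after their values were seen.

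The alternatives were DESeq2 1.42.0, RLE scaling, no filter, a filter of 1 CPM in 6 libraries, a replicate block, the compared groups alone, limma voom with quality weights, 1 surrogate variable (sva 3.50.0), an adjusted p of 0.1 and leaving out each library in turn. Added after the data were seen were leaving out control replicate 1 of both labelled sexes, Y-linked expression as a covariate, and offsets that remove each library's smooth trend with GC content. Same-numbered libraries of different groups were checked for pairing by correlating their deviations from group means. The 3 libraries of each group were compared in pairs for duplicates, and chi-square over degrees of freedom was 2.39 to 12.6, so none agreed within sampling noise.

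The tests were tried on simulated counts drawn from the means and dispersions over all 12 libraries, with 200 changed genes in the labelled-female contrast. In the fit of 12 libraries (17456 genes), 24 percent of genes changed 1.2-fold were recovered, 56 percent at 1.5-fold, 70 percent at 2-fold and 92 percent at 4-fold, with 4 false calls. In the simulated fit of labelled-female libraries alone (16977 genes), the shares were 24, 54, 70 and 94 percent with 9 false calls. Every simulated library had the same dispersions, whereas the real common biological coefficient of variation was 0.0508 in labelled-female and 0.0785 in labelled-male libraries. The similar shares therefore follow from the simulation, and they do not describe the real fit of labelled-female libraries alone. With no simulated change (17419 genes), 0 genes and 0 of 38 lists were called. Each gene was drawn independently, so the simulation cannot show how often lists are falsely called where genes vary together.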

Results

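Gene expression was measured by RNA sequencing in the dorsal hippocampus of mice at postnatal day 7. The control genotype, SERTfl/fl, carries loxP-flanked copies of Slc6a4, the gene of the serotonin transporter that takes serotonin back into cells. In the other genotype, SERTPyramid, that gene is conditionally deleted in pyramidal neurons. Each of 12 libraries was made from tissue pooled from 4 mice, with 3 libraries for each combination of genotype and labelled sex. The deposited tables hold raw counts for 52634 genes, and library totals ran from 18747249 to 25522347 counts. Whether pools shared mice or litters is not given in the sources used here, so p-values measure the spread between these libraries.

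Sex-chromosome transcripts went against the labelled sex in 10 of the 12 libraries. Xist, the X-linked RNA that silences 1 X chromosome in female cells (X, 103460366 to 103483254, GRCm38), reached 20646 counts in control replicate 1 labelled female. The other control libraries labelled female had 59 and 527 Xist counts, and the SERTPyramid libraries labelled female had 46, 13 and 15. Summed counts of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were 1 in control replicate 1 labelled female, against 3059, 2849, 3151, 2957 and 2908 in the other 5 libraries labelled female. Among libraries labelled male, control replicate 1 had 14 Xist counts and 2159 Y-linked counts. The other 5 libraries labelled male had 16794 to 22750 Xist counts and 0 to 6 Y-linked counts. Female and male therefore name the label of a library throughout, and no library was moved to another group. Every comparison of genotypes or sexes was also computed without control replicate 1 of both labelled sexes, a choice made after the values were seen.

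**Figure D1:**
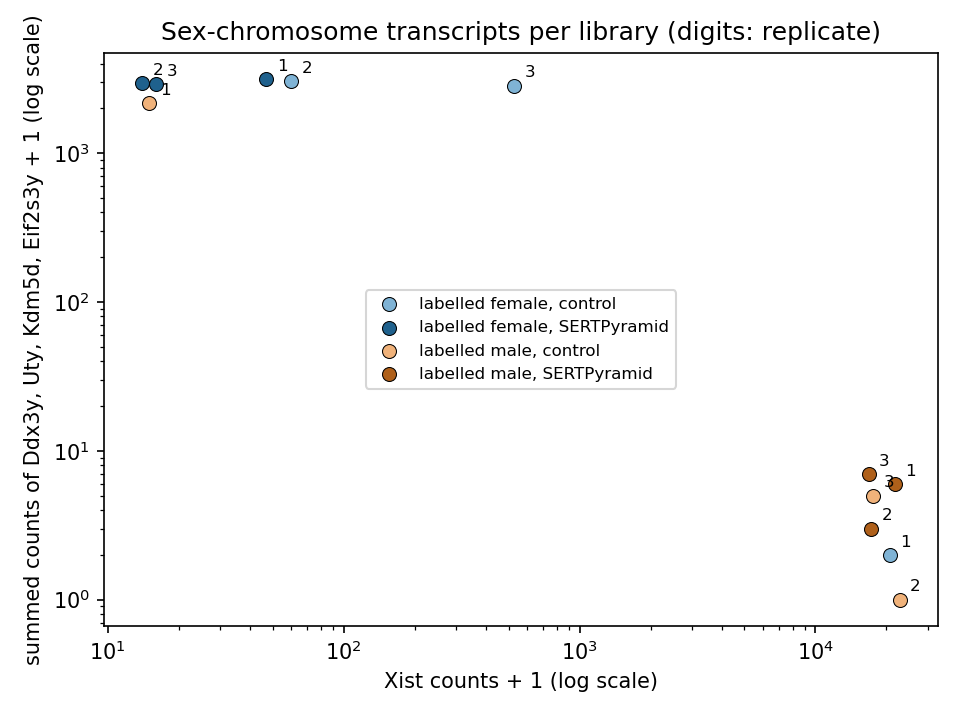
Xist counts against the summed counts of 4 Y-linked genes in each of 12 libraries, both plus 1 on log scales, with colours for group and digits for replicate number. Control replicate 1 labelled female sits with the libraries labelled male at 16794 or more Xist counts, and control replicate 1 labelled male sits with the libraries labelled female at 2159 or more Y-linked counts.

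Slc6a4 itself (ENSMUSG00000020838, chromosome 11, 76998603 to 77032340, plus strand) was close to the detection limit in every library. Labelled-female controls had 5, 16 and 9 counts, a mean of 0.431 ± 0.234 CPM (SD, n = 3), and labelled-female SERTPyramid libraries had 12, 3 and 1 counts, a mean of 0.219 ± 0.226 CPM (SD, n = 3). Labelled-male controls had 0, 17 and 12 counts, a mean of 0.388 ± 0.346 CPM (SD, n = 3), and labelled-male SERTPyramid libraries had 8, 3 and 7 counts, a mean of 0.257 ± 0.113 CPM (SD, n = 3). The 0 in control replicate 1 labelled male allows up to 0.160 CPM, the level of 3 counts. Neither difference exceeded the spread between libraries in 2-sided exact permutation tests (p = 0.40 among labelled females and 0.50 among labelled males), where 3 against 3 libraries cannot give less than 0.10. Permuting genotype within both labelled sexes together gave an exact p of 0.23, against a smallest possible 0.005. In edgeR's quasi-likelihood test the log2 fold change was -0.93 ± 0.80 (SE, adjusted p = 0.811) among labelled females and -0.70 ± 0.79 (SE, adjusted p = 0.999) among labelled males. A count over the whole gene takes in reads from undeleted exons and from cells outside the deletion, so it checks the genotype labels only weakly. The loss of Slc6a4 was not detectable at this depth.

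**Figure D2:**
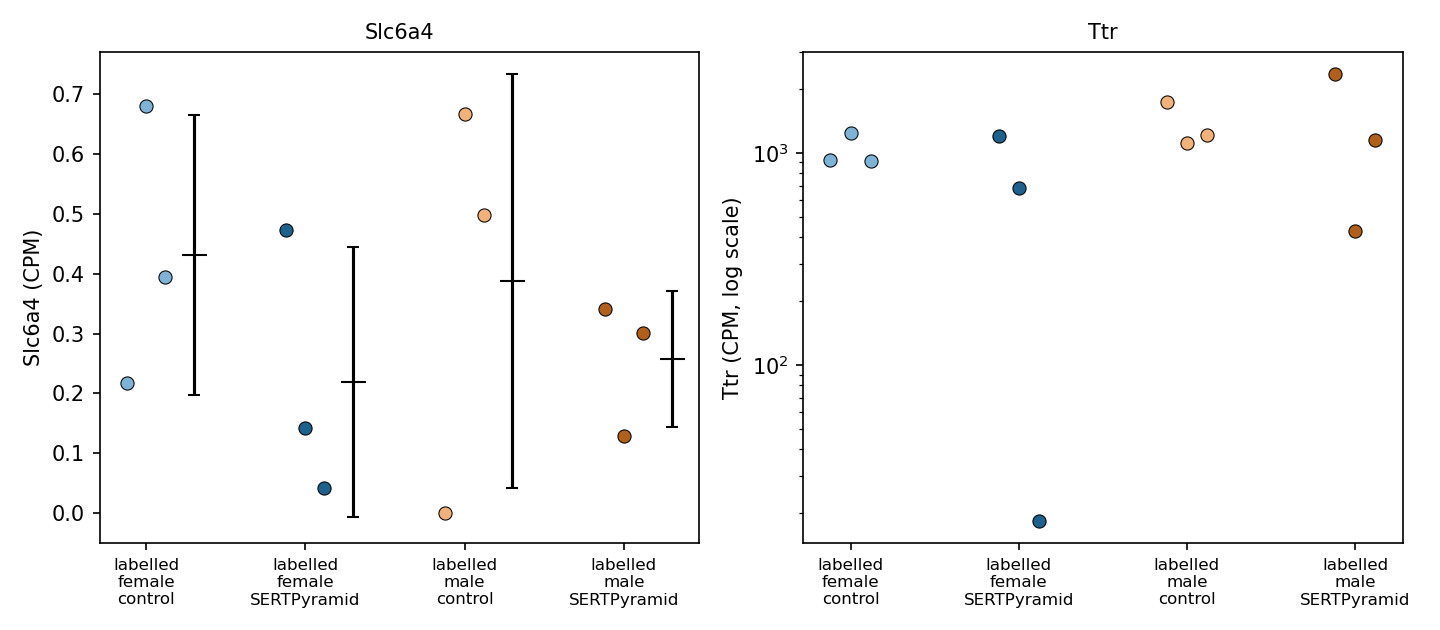
Slc6a4 in CPM (left) and Ttr in CPM on a log scale (right) in each library by labelled sex and genotype, with points for libraries and, at left, mean ± SD bars. Slc6a4 reaches at most 0.681 CPM, and Ttr is lowest, at 18.4 CPM, in SERTPyramid replicate 3 labelled female.

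The first comparison asked which genes differ between SERTPyramid and control libraries labelled female. In the planned fit of all 12 libraries Col6a2 (ENSMUSG00000020241, chromosome 10, 76595762 to 76623630), a collagen VI chain gene, had 17.7 ± 1.61 CPM in controls and 24.0 ± 1.25 CPM in SERTPyramid (SD, n = 3), with a log2 fold change of 0.44 ± 0.09 (SE, adjusted p = 0.530 by edgeR). Ppia, the cyclophilin A gene, had 75.9 ± 3.90 and 63.6 ± 4.53 CPM (SD, n = 3), with a log2 fold change of -0.26 ± 0.06 (SE, adjusted p = 0.530 by edgeR), though Ppia can share reads with processed copies. No gene passed an adjusted p of 0.05 in edgeR, and the other genes with the smallest p were Capn15, Vars2, Fbln5, Bcan, Lmtk3, Rbm12b1, Mib1 and Suco. That fit gave 1417 genes at an unadjusted p under 0.05, against 882 expected by chance over 17631 genes, while limma voom called 0 and DESeq2 1, Xist (adjusted p = 0.0439). Xist had 20646 counts in control replicate 1, whose sex-chromosome transcripts differ from those of the other labelled-female libraries. It had 59 and 527 counts in the other controls and 46, 13 and 15 in SERTPyramid. Without a low-count filter edgeR called 103 genes, and with the 6 labelled-female libraries fitted alone it called 415.

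In the camera test with a preset correlation, 8 of 38 lists were called lower in labelled-female SERTPyramid libraries and 0 higher. With an estimated correlation none was called (adjusted p = 0.971 for each). The 8 lists were choroid plexus epithelium (median log2 fold change -0.48 over 15 genes, 15 below 0), red blood cells (-0.30), dentate granule neurons (-0.16), genes escaping X inactivation (-0.15), endothelial cells (-0.13), presynaptic release (-0.08), axon guidance (-0.06) and GABA receptors and transport (-0.04). Of the 12 dentate granule genes, C1ql2 (-0.33), Prox1 (-0.25) and Stxbp6 (-0.18) passed when adjusted over the list alone, as did the haemoglobin gene Hbb-bt (-0.40) of the red blood cell list, and 0 passed over all genes. The choroid plexus list was not called without SERTPyramid replicate 3 labelled female, where its median log2 fold change was -0.02. The X-escape list was not called without control replicate 1 labelled female (median -0.01), where Xist stood at 897 CPM against 2.51 and 23.1 CPM in the other controls, nor without SERTPyramid replicate 1 (-0.19) or 3 (-0.13). Leaving out each of the 6 libraries, the dentate granule and axon guidance lists lost their call in 1 fit each. The red blood cell, endothelial, presynaptic and GABA lists lost theirs in 2 each. Without control replicate 1 labelled female 3 lists were called, and with 1 surrogate variable 5, of which 2 were higher and 3 lower.

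When the 6 labelled-female libraries were fitted alone, an alternative fixed beforehand, edgeR called 415 of 17108 genes, 282 higher and 133 lower in SERTPyramid. Leng8 (ENSMUSG00000035545, chromosome 7, 4137039 to 4148177) rose from 161 ± 12 to 258 ± 10.2 CPM (SD, n = 3), a log2 fold change of 0.69 ± 0.05 (SE, adjusted p = 1.33e-07 by edgeR). Mbd6 (ENSMUSG00000025409, chromosome 10, 127281956 to 127289018), which encodes a methyl-CpG-binding domain protein, rose from 40.6 ± 1.1 to 63.3 ± 4.14 CPM (SD, n = 3), by 0.64 ± 0.05 on the log2 scale (SE, adjusted p = 1.33e-07 by edgeR). In the fit of all 12 libraries these genes had adjusted p of 0.696 and 0.568 by edgeR. Among the genes with the largest increases were the cardiac myosin gene Myh6 (log2 fold change 0.96), Leng8, Rbm12b1 (0.68), the glypican gene Gpc2 (0.64), Mbd6, the complement gene C4b (0.62), Grin1os (0.59), Ap1g2 (0.58) and the kinase gene Mapk15 (0.53). C4b shares sequence with a close paralog and Grin1os lies antisense to another gene, so reads counted without strand cannot be assigned to them with certainty. The largest decreases were Ccm2l (-0.80), the elastic-fibre gene Fbln5 (-0.49), Lsr (-0.46), Sypl2 (-0.45), the transcription factor gene Onecut2 (-0.39), Gucy1a2 (-0.37), Slc35a3 (-0.37), the globin-family gene Cygb (-0.37), Pnrc1 (-0.33) and the synaptic organizer gene C1ql2 (-0.33). DESeq2 on the same 6 libraries called 336 genes and limma voom 306. The count was 251 without control replicate 1, 158 without control replicate 2 and 136 without SERTPyramid replicate 2. With GC offsets 291 genes were called, 230 of them among the 415. Of 9 splits of the labelled-male libraries other than the labelled genotype, the one with the most calls exchanged control replicate 1 and SERTPyramid replicate 2. It called 310 genes. With SERTPyramid replicates 1 and 3 and control replicate 1 set over the rest, 117 of these were among the 415 in the same direction.

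Among the lists fixed beforehand, members called in the labelled-female libraries alone went in both directions. With the preset correlation camera called the 8 lists of the 12-library fit lower there too (adjusted p from 0.000124 for choroid plexus to 0.00945 for red blood cells and X-escape genes). With an estimated correlation none was called (adjusted p = 0.956 for each). Of 23 presynaptic release genes, Pclo (-0.14) fell, 7 fell and 1 rose when p was adjusted over the list alone, and 19 lay below 0 in all. Of 19 genes of GABA receptors and transport, Gabra2 (-0.16), a receptor subunit, fell, with 5 decreases adjusted over the list alone. Of 40 axon guidance genes, the semaphorin gene Sema5a (-0.29) fell and the plexin gene Plxna3 (0.24) rose, with 5 decreases and 1 increase adjusted over the list alone. The oligodendrocyte precursor genes Cspg4 (0.22) and Sox10 (0.19) and the astrocyte genes Gfap (0.16) and Fgfr3 (0.19) rose, as did Bcan (0.25), a proteoglycan of the perineuronal matrix. The immature-neuron genes Dcx (-0.15) and Neurod1 (-0.24), the NMDA receptor subunit gene Grin2b (-0.20) and the haemoglobin gene Hbb-bs (-0.32) fell. Members above 0 were 9 of 15 immature-neuron genes, 12 of 24 glutamate receptor genes, 8 of 16 astrocyte genes, 6 of 10 oligodendrocyte precursor genes, 5 of 14 perineuronal matrix genes and 1 of 6 red blood cell genes. Hbb-bs shares sequence with other globin genes.

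**Figure D3:**
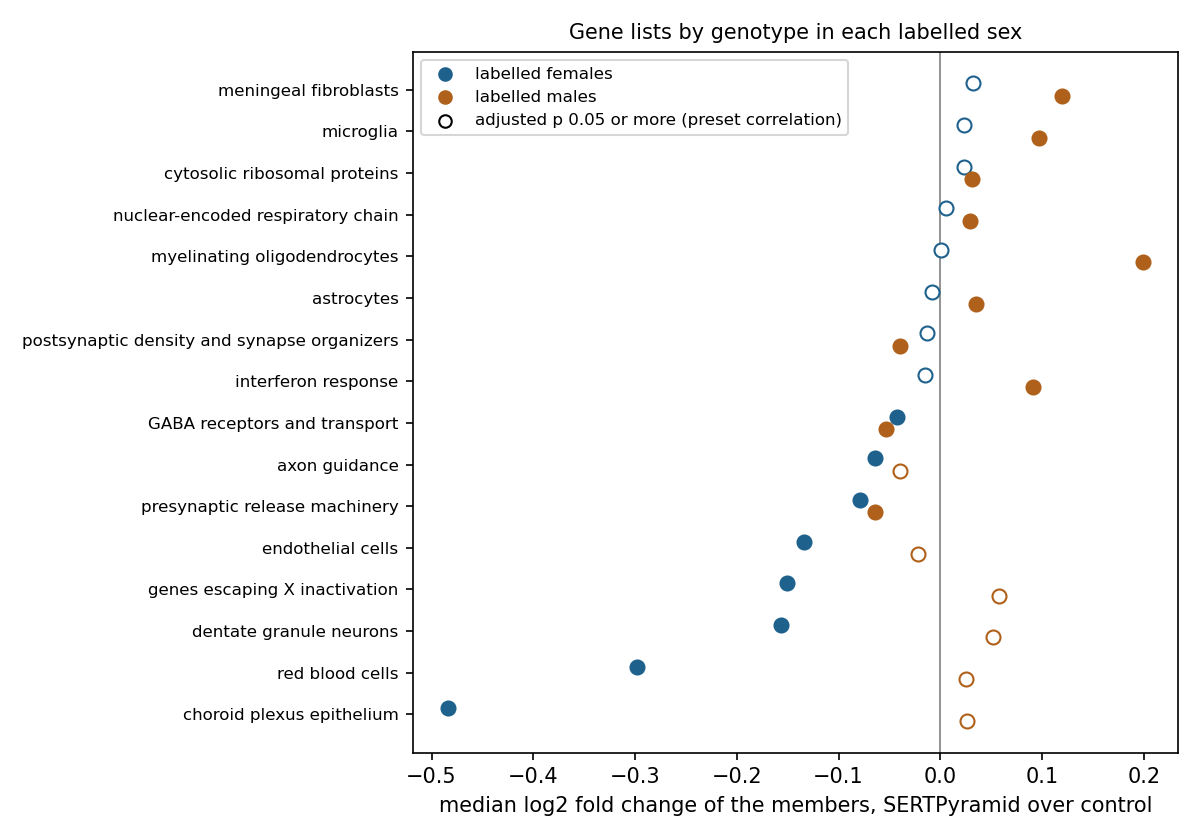
Median log2 fold change (SERTPyramid over control) of each gene list called in either labelled sex, with blue points for labelled females and brown for labelled males, filled where the preset-correlation adjusted p is below 0.05. Choroid plexus epithelium lies at -0.48 among labelled females and 0.03 among labelled males, and with an estimated correlation no list is called.

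The second comparison asked the same of libraries labelled male. No gene passed, and the genes with the smallest p included C1ql2, Fbxo2, Marveld1, Pogk, Acta2, Cntnap4, Meaf6, Gjb2 and Slc16a14. C1ql2 (ENSMUSG00000036907, chromosome 1, 120340582 to 120343174), a marker of dentate granule neurons, had 14.2 ± 1.39 CPM in controls and 19 ± 1.34 CPM in SERTPyramid (SD, n = 3), a log2 fold change of 0.42 ± 0.10 (SE, adjusted p = 0.999 by edgeR). Fbxo2, an F-box protein gene, had 35.4 ± 1.47 and 41.8 ± 3.60 CPM (SD, n = 3), a log2 fold change of 0.24 ± 0.07 (SE, adjusted p = 0.999 by edgeR). The fit of 12 libraries gave 558 genes at an unadjusted p under 0.05 and the fit of the 6 labelled-male libraries alone 317, and edgeR, DESeq2 and limma voom called 0 in both fits. Without a low-count filter edgeR called 5 genes. Without control replicate 1 of both labelled sexes, 0 genes passed here and among labelled females.

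Among 38 lists, the preset-correlation camera test called 7 higher and 3 lower in labelled-male SERTPyramid libraries. With an estimated correlation no list was called (adjusted p = 0.853 for 9 of them and 0.889 for ribosomal proteins). Myelinating oligodendrocyte genes had a median log2 fold change of 0.20, with 13 of 14 above 0, including Mag (0.58 ± 0.22 SE) and Cnp (0.15 ± 0.07 SE). Meningeal fibroblast genes (0.12), microglial genes (0.10), interferon response genes (0.09), astrocyte genes (0.04), cytosolic ribosomal protein genes (0.03) and nuclear-encoded respiratory chain genes (0.03) were also called higher. Presynaptic release (-0.06), GABA receptors and transport (-0.05) and postsynaptic density genes (-0.04) were called lower. No member of these 10 lists passed over all genes or adjusted over the list alone. The choroid plexus list, not called here, had a median of 0.03 and a test direction of lower, and without SERTPyramid replicate 1 labelled male it was called lower (adjusted p = 0.000265, the lowest of 0.000265 to 0.738 over left-out libraries). Leaving out each of the 6 labelled-male libraries, every one of the 10 called lists lost its call in 2 to 4 fits. Without control replicate 2 labelled male 6 lists were called. Medians changed sign for astrocytes without SERTPyramid replicate 1 (-0.0002), for ribosomal proteins without control replicate 2 (-0.0077) or SERTPyramid replicate 3 (-0.013), and for postsynaptic genes without SERTPyramid replicate 3 (0.012).

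The third comparison was the interaction, whether the genotype difference itself differed between the labelled sexes. C1ql2 was lower in SERTPyramid among labelled females and higher among labelled males, with an interaction log2 fold change of -0.75 ± 0.14 (SE, adjusted p = 0.585 by edgeR). Over labelled-female libraries its CPM went from 17.7 ± 2.29 to 14.0 ± 0.840 (SD, n = 3), opposite to the labelled-male values above. DESeq2 called C1ql2 alone (adjusted p = 0.0363), and it passed in edgeR adjusted over the 12 dentate granule genes alone. Fbln5 (chromosome 12, 101746565 to 101819055) had 9.62 ± 0.843 and 6.82 ± 0.847 CPM among labelled females and 9.23 ± 0.629 and 11.3 ± 1.2 CPM among labelled males (SD, n = 3). Its interaction log2 fold change was -0.79 ± 0.16 (SE, adjusted p = 0.696 by edgeR). Next by p, none passing, came Slc18a3, Cpeb2, Slc25a16, Adamts16, Evpl, Glcci1, Vapa and Aire. edgeR called 0 genes, with 785 at an unadjusted p under 0.05, and limma voom called 0, while 14 were called without a low-count filter.

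**Figure D4:**
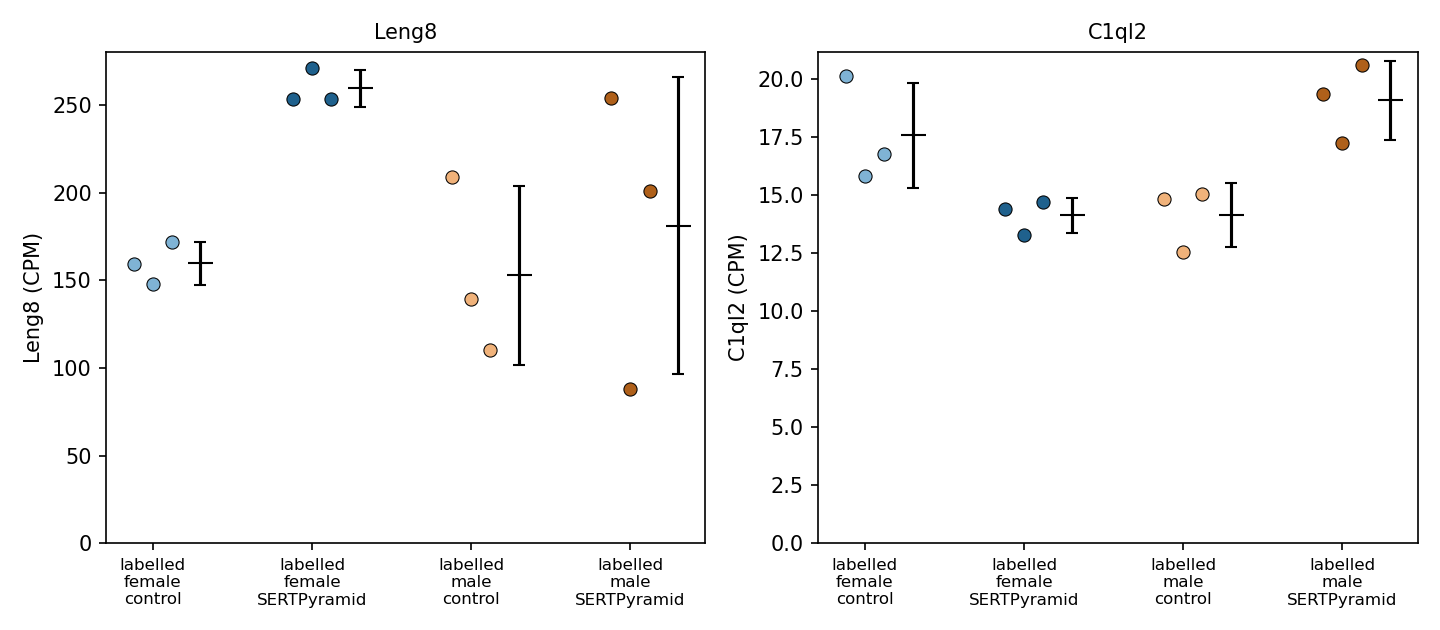
Leng8 (left) and C1ql2 (right) in CPM in each library by labelled sex and genotype, with points for libraries and mean ± SD bars. Leng8 lies at 148 to 172 CPM in labelled-female controls and 254 to 272 CPM in labelled-female SERTPyramid libraries, and at 88.1 to 254 CPM in labelled-male SERTPyramid libraries.

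In the preset-correlation camera test, 6 lists differed in the interaction, all lower in labelled females relative to labelled males. With an estimated correlation no list was called (adjusted p = 0.986 for each). The 6 lists were dentate granule neurons (median -0.24, 11 of 12 below 0), choroid plexus epithelium (-0.51), red blood cells (-0.34), genes escaping X inactivation (-0.18), myelinating oligodendrocytes (-0.16) and endothelial cells (-0.10). Examples are Prox1 (-0.29 ± 0.11 SE), the dentate granule transcription factor gene, and Slc2a1 (-0.26 ± 0.09 SE), the endothelial glucose transporter gene. The X-escape list holds Xist, whose counts went against the labelled sex in 10 libraries, and was not called without control replicate 1 labelled female (-0.09) or control replicate 1 labelled male (-0.09), among others. Leaving out each of the 12 libraries, every one of the 6 lists lost its call in 1 (dentate granule) to 6 (myelinating oligodendrocytes) fits. The count was 3 without control replicate 1 or SERTPyramid replicate 3 labelled female and 14 without SERTPyramid replicate 3 labelled male, and the choroid plexus median was 0.18 without SERTPyramid replicate 1 labelled male.

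Averaged over the labelled sexes, no gene passed (smallest adjusted p = 0.756), 1145 genes had an unadjusted p under 0.05, and DESeq2 and limma voom called 0. The genes with the smallest p were the collagen VI genes Col6a1 (0.25 ± 0.06 SE) and Col6a2 (0.29 ± 0.07 SE), then Ppia, Tars2, Man2b1, Usp19, Hps4, C4b, Gfap and Pias2. Gfap, the astrocyte filament gene, had a log2 fold change of 0.14 ± 0.03 (SE) and C4b 0.47 ± 0.11 (SE). The count was 144 without SERTPyramid replicate 2 labelled male, with 131 higher and 13 lower. Of the lists, presynaptic release (-0.06), choroid plexus epithelium (-0.24), GABA receptors and transport (-0.07) and axon guidance (-0.04) were called lower, and cytosolic ribosomal proteins (0.03), myelinating oligodendrocytes (0.12) and microglia (0.08) higher, with the preset correlation. With an estimated correlation none was called (adjusted p = 0.806 for each). The count of lists was 14 without SERTPyramid replicate 1 labelled male and 12 without a low-count filter.

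Across all 17631 genes, the genotype log2 fold changes among labelled females and labelled males had a Pearson correlation of 0.029 (genes are not independent replicates). Among the 415 genes called in the labelled-female libraries alone, 318 had the same sign in the labelled-male libraries alone. This was 76.8 percent of those tested in both, against 54.0 percent of all genes tested in both. The split of the labelled-male libraries with the most calls exchanged control replicate 1 and SERTPyramid replicate 2. With SERTPyramid replicates 1 and 3 and control replicate 1 set over the rest, 89.4 percent of the genes called among labelled females had the same sign. Over 16803 genes its changes had a Pearson correlation of 0.196 with the labelled-female changes. That split was picked for its number of calls, and no same-sign share over all genes was taken for it. The interaction had an unadjusted p under 0.05 by edgeR for 117 of the 415, against 785 of all 17631 genes, and 0 passed over all genes. The 415 were selected for their labelled-female change, which is part of the interaction, so a raised share is built in. In the labelled-male libraries alone the median log2 fold change in the labelled-female direction was 0.06, against a median absolute change of 0.23 among labelled females.

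Comparing the labelled sexes within a genotype, no gene passed in controls (smallest adjusted p = 0.974, 833 genes at an unadjusted p under 0.05, DESeq2 and limma voom 0). In SERTPyramid libraries 0 passed, with Fbln5 nearest (-0.73 ± 0.11 SE, adjusted p = 0.0620 by edgeR), 1494 genes at an unadjusted p under 0.05, 0 by limma voom and 41 by DESeq2. After Fbln5 came Sf3a1 (-0.35), Igfbp3 (-0.43), Fbln1 (-0.41), Cpeb2 (-0.37), Neurod1 (-0.38), Rcn2 (-0.31), Pnrc1 (-0.72), Chpf2 (0.30) and Tmem107 (-0.58), labelled female over labelled male. In controls the genes with the smallest p were Elof1 (-0.26), Mctp1 (0.24), Ccdc51 (-0.63), Gpcpd1 (0.20), Banp (-0.25), Cep85l (0.28), Aire (1.87), Plekhb1 (-0.24), Phlda1 (-0.31) and Zfp94 (-0.41). Without control replicate 1 of both labelled sexes, 7 genes passed in controls and 11 in SERTPyramid. In controls these were the Y-linked Kdm5d, Ddx3y, Eif2s3y, Uty and Gm29650, higher in libraries labelled female, and the X-linked Eif2s3x (-0.58 ± 0.07 SE) and Kdm5c (-0.41 ± 0.07 SE), lower there. In SERTPyramid the autosomal genes among the 11 were Fbln5, Igfbp3 and Sf3a1. A fit of the 6 SERTPyramid libraries alone called 7 genes, all on the sex chromosomes, among them Kdm5d (8.64 ± 0.18 SE) and Xist (-9.56 ± 0.30 SE). These did not pass in the fit of 12. There each control group held libraries with Xist and libraries with Y-linked transcripts, which widens the spread estimate that all groups share for such genes. Separately, the fit of 12 libraries called 139 genes in SERTPyramid without SERTPyramid replicate 1 labelled male, in place of 0.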

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

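The tests of explanations for the choroid plexus list, the sex-chromosome transcripts and the labelled-female libraries alone were chosen after these results were seen, as were the splits of the labelled-female libraries alone; the nuclear-transcript list was fixed before its own values were seen.

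A closer look was given to 6 gene lists whose genotype difference differed between the labelled sexes in the camera interaction test with a preset correlation. Adjusted p was 0.000965 for dentate granule neurons, 0.0284 for choroid plexus epithelium, 0.0339 for genes escaping X inactivation, 0.0339 for red blood cells, 0.0339 for endothelial cells and 0.0454 for myelinating oligodendrocytes. With an estimated correlation each had an adjusted p of 0.986. Among 100 relabellings of genotype within labelled sexes, the real one included, 83 called at least 6 lists and the highest other called 19, so chance cannot be excluded for the number of lists.

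The choroid plexus list was called lower in SERTPyramid libraries labelled female and was not called in those labelled male, where it was called lower once SERTPyramid replicate 1 was left out (adjusted p = 0.000265). Ttr ranged from 18.4 CPM in SERTPyramid replicate 3 labelled female to 2356 CPM in SERTPyramid replicate 1 labelled male. Its deviations from group means followed those of the other 14 members (Pearson r = 0.977), and across the 12 libraries r was 0.980 (permutation p = 1e-05, the smallest that was allowed) and Spearman's rho 0.930 (permutation p = 4e-05), with r = 0.953 without the 2 libraries farthest from the median. A candidate explanation is choroid plexus tissue carried along in dissection in differing amounts. The interaction adjusted p was 0.606 without SERTPyramid replicate 3 labelled female and 0.613 without SERTPyramid replicate 1 labelled male (range over left-out libraries 8.39e-07 to 0.613), so the call rests on these 2 libraries, and an effect of genotype or sex stays open.

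Sex-chromosome transcripts went against the label in 10 libraries, 2 labelled female and 2 labelled male among controls and 3 and 3 among SERTPyramid. Equal numbers in both labelled sexes are consistent with labels exchanged between them, and which of the labels or columns moved remains open. Pools holding mice of both sexes are argued against, since the minor signal was at most 2.49 percent of the highest library, in control replicate 3 labelled female, where 1 mouse in a pool of 4 would give 1 part in 4. Reads from X-linked paralogs are argued against too, since the Ddx3y share of Ddx3x counts differed at least 472-fold between libraries, with Ddx3y counts under 3 per library set to 3. No biological explanation was tested.

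The fit of the labelled-female libraries alone called 415 genes and the fit of 12 libraries 0. GC content bias as the whole cause is argued against, since with GC offsets the median change of these genes went from 0.23 to 0.21 on the log2 scale, 89.4 percent of its size, although 230 of the 415 stayed called. The log2 fold changes of the 415 were alike in both fits (median ratio 0.9965), so the calls were lost through the SE, not the size of change. A larger spread of the libraries labelled male stays open as a source of the count of 0. Over 17108 genes, the median of the per-gene ratios of SE, fit of 12 over fit of 6, was 1.09. That is under the bound of 1.1 set for excluding a larger spread. The common biological coefficient of variation, however, was 0.0785 in the labelled-male and 0.0508 in the labelled-female libraries. The median ratio of 1.61 over the 415 decides nothing, as these were selected for a small SE in the fit of 6. A list of 25 measured nuclear and intron-retaining transcripts had a median log2 fold change of 0.05 (99.8th percentile of matched random lists) and 0.01 among labelled males. Of its members 1 was called, against 415 of 17108 genes. The random lists were matched on expression only, so members that vary together between libraries can reach a high percentile whatever the cause. The split of the libraries labelled male with the most calls (SERTPyramid replicates 1 and 3 with control replicate 1) called 310 genes. It shared 117 of the 415 in the same direction, where independent lists would share 7.64 in either direction. The 7.64 takes genes to be called independently and with equal ease, and the split was picked for its number of calls. The excess over it therefore measures no cause. This split differs from the labelled genotype only in exchanging control replicate 1 and SERTPyramid replicate 2. An axis of RNA composition that varies among libraries may hold part of the 415. The split cannot tell such an axis from genotype, nor from genotype labels exchanged between those libraries. Genotype stays open for these genes. The 10 splits of 6 libraries are too few for a share under 0.05, with 415 for the real split, 1 split as large, and 3 for the highest other.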

How the results depend on the processing

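The alternatives that left out control replicate 1 of both labelled sexes, added Y-linked expression or GC offsets, or refitted labelled-female libraries with another tool were chosen after the data were seen. Where a count moved, the cause was not tested, apart from the mixed control groups described above for sex-chromosome genes. Without a low-count filter, 103 genes were called among labelled females (77 higher), 5 among labelled males, 14 in the interaction, 66 averaged (60 higher), 3 between labelled sexes in controls and 220 in SERTPyramid. Fitting only the groups compared gave 415 genes among labelled females in place of 0 and 7 between the labelled sexes in SERTPyramid, where DESeq2 gave 41, an adjusted p of 0.10 gave 3 and leaving out the 2 control libraries gave 11, against 7 in controls. DESeq2 gave 1 gene among labelled females and 1 in the interaction. The counts by RLE scaling, the stricter filter, limma voom and 1 surrogate variable stayed at 0.

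Leaving out each library gave 0 genes among labelled females, labelled males, in the interaction and between labelled sexes in controls, 0 to 144 averaged (144 without SERTPyramid replicate 2 labelled male) and 0 to 139 between labelled sexes in SERTPyramid (139 without SERTPyramid replicate 1 labelled male). In the labelled-female libraries alone the range was 136 to 464, and in the labelled-male libraries alone 0. Slc6a4 ranged from -2.21 to -0.43 among labelled females and -1.18 to -0.11 among labelled males, never past the threshold. The correlation of changes, 0.029, was 0.076 with voom, 0.098 without the 2 control libraries and -0.0076 to 0.116 leaving out each library.

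Of 31 list results called, 31 were lost with an estimated correlation and 31 with fry, giving 0 lists in each comparison. List counts were 12 averaged without a filter, 12 without the 2 control libraries and 11 with Y-linked expression; among labelled females 5 with a surrogate variable and 3 without the 2 control libraries. Leaving out each library gave 3 to 9 among labelled females (3 without control replicate 1), 6 to 12 among labelled males (6 without control replicate 2), 3 to 14 in the interaction (3 without labelled-female control replicate 1 or SERTPyramid replicate 3, 14 without labelled-male SERTPyramid replicate 3) and 7 to 14 averaged (14 without labelled-male SERTPyramid replicate 1). Medians that changed sign were astrocytes (-0.0002) and, in the interaction, choroid plexus (-1.05 to 0.18 over left-out libraries), both without labelled-male SERTPyramid replicate 1, ribosomal proteins (-0.0127 to 0.085, with -0.0077 without labelled-male control replicate 2 and the lowest without SERTPyramid replicate 3) and postsynaptic genes (-0.0559 to 0.0119, the highest without SERTPyramid replicate 3).

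No pairing by replicate number was seen, though 3 pairs per comparison are too few to exclude it. Correlations of same-numbered deviations ran from -0.225 to 0.234, and in no comparison did every library correlate best with its own number. With the replicate block, 2 genes were called between the labelled sexes in SERTPyramid. In the labelled-female libraries alone 689 were called in place of 415, and 521 with the block and GC offsets. Depth limits Slc6a4, at 0 to 17 counts per library.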

Other observations

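The splits of the labelled-male libraries alone and the GC and interaction counts for the 415 genes were chosen after the results were seen.

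Between the labelled sexes in controls, camera with the preset correlation called 3 lists, 1 higher and 2 lower in controls labelled female, and 0 with an estimated correlation. Each control group mixed libraries with Xist and libraries with Y-linked transcripts. GABAergic interneuron genes were called lower (median -0.08, 14 of 18 below 0, camera adjusted p = 0.0415 with the preset and 0.851 with an estimated correlation). Ependymal genes were lower in controls labelled female than in controls labelled male (median log2 difference -0.50, 11 of 11 below 0, camera adjusted p = 2.21e-06 with the preset and 0.851 with an estimated correlation). Foxj1, the regulator of motile cilia, had 20.7 and 30.7 CPM, and Rsph1, a cilium component gene, 3.36 and 5.76 CPM. Choroid plexus genes, of neighbouring ventricular tissue, had a median of -0.43 in the same comparison, with 15 of 15 below 0, and were not called (adjusted p = 0.111 with the preset and 0.851 with an estimated correlation). In SERTPyramid libraries 10 lists were called lower in libraries labelled female with the preset and 0 with an estimated correlation. Of these, cell cycle genes (median -0.08, 24 of 24 below 0, Pcna -0.19) and immature-neuron genes (-0.11, 12 of 15 below 0, Neurod1 -0.38) had adjusted p of 0.000805 and 0.000687 with the preset and 0.816 for both with an estimated correlation. Choroid plexus genes had a median of -0.88 there (adjusted p = 6.54e-07 with the preset and 0.816 with an estimated correlation). Ttr in replicates 1 to 3 was 1197, 679 and 18.4 CPM labelled female and 2356, 430 and 1147 CPM labelled male. The list was not retested without single libraries in this comparison. The SERTPyramid libraries labelled female all carried Y-linked transcripts, and those labelled male all carried Xist, which bears on the X-escape list. The other medians were -0.28 for genes escaping X inactivation, -0.26 for ependymal cells, -0.21 for interferon response, -0.15 for meningeal fibroblasts, -0.13 for endothelial cells, -0.09 for heat shock and unfolded protein response and -0.03 for the respiratory chain (adjusted p from 1.69e-05 to 0.0214 with the preset and 0.816 to 0.904 with an estimated correlation).

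Tbkbp1 ranged from 1116 CPM in control replicate 2 labelled male to 4782 CPM in SERTPyramid replicate 3 labelled male. Among the 415 genes of the labelled-female fit, median GC content was 55.7 percent for those that rose and 44.6 percent for those that fell, against 49.6 percent for all genes. Adjusted over those genes alone, the interaction called 2, C1ql2 and Fbln5 having the smallest p, but these genes were selected for their labelled-female change, so the count is not independent evidence.

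The splits of samples below test whether other groupings of the same libraries give results as large. For the interaction, 37 of 100 relabellings gave at least the real 785 genes at an unadjusted p under 0.05 (highest other 2419), and for the averaged genotype 25 of 100 gave at least 1145 (highest other 3522), so chance cannot be excluded for either. It cannot be excluded for the 7 averaged lists (78 of 100, highest other 20) nor for the correlation of changes (81 of 100 as large in size, highest other 0.180). The 10 splits of 3 against 3 libraries are too few for a share under 0.05. Genes at an unadjusted p under 0.05 were 1417 among labelled females (1 split as large, highest other 685), 558 among labelled males (8 splits, highest other 3161), 833 between labelled sexes in controls (2 splits, highest other 1075) and 1494 in SERTPyramid (2 splits, highest other 1914). Lists called were 8 among labelled females (6 splits, highest other 12) and 10 among labelled males (6 splits, highest other 23). Genes called in the labelled-male libraries alone were 0 (10 splits, highest other 310). The split with 310 exchanges control replicate 1 and SERTPyramid replicate 2. It cannot tell a structure of these samples from genotype labels exchanged between those libraries.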
